A study of Mus musculus with 6 samples.

How the data were processed

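The series holds 6 RNA-seq libraries of MSCs from mouse alveolar bone, 3 from WT and 3 from Ccrl2-KO mice, with groups and replicate numbers taken from the sample titles and the genotype label. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra RNA kit. The labels do not say that strand was kept, so reads of overlapping or antisense genes may be shared. The submitters' processing notes name HISAT2, StringTie and SAMtools, with neither versions nor roles, and the mm9 build. The read counter is not given in the sources used here.

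The authors deposited 1 table of counts per gene for all libraries, with whole-number values that were not normalized. The deposited table also has gene names, coordinates, biotypes and a gene length (a number of another kind than the counts), which was used only in a check of length. No row without a gene entered the table's totals. Each column's name gave the genotype and replicate number and matched 1 sample title, apart from the word Ctrl, whose meaning is not given in the sources used here. Coordinates differ from the mm9 build named in the notes. Of 54409 identifiers found in GENCODE M21, 53499 (98.3%) had the same start and end there, so positions are given as GRCm38.

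Counts per library were 17268692, 16114974 and 18244287 for WT replicates 1 to 3 and 16532076, 16225227 and 18616433 for KO replicates 1 to 3. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.161 to 0.186 CPM (counts as a share of the library total, as edgeR scales them), and such floors cover counting error only. Replicates were compared before use. The chi-square per gene between libraries of 1 group lay between 4.54 and 62.9, so no library repeated another. Genes with near-identical copies are uncertain. Gapdh, for example, had 83 to 125 counts per library against 60509 or more for Actb.

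Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with robust moderation, genotype as the only term, TMM scaling, and genes kept by filterByExpr with a minimum count of 10 and total of 15. Benjamini-Hochberg adjustment covered all 13705 tested genes, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries. Of 44 gene lists fixed before the data were examined, 32 of function and 12 of cell type markers, 39 had at least 4 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists, beside camera with an estimated correlation and fry. A fry p tests whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. The mean of a list is that of its members' differences in log2 CPM.

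Genes were named by a rule fixed before the data were examined. It took Ccrl2, the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM and groups that did not overlap, leaving out predicted-gene symbols, then the 5 called genes of highest CPM, and the 3 members of smallest p in each called list and in the osteoblast, NF-kB and Wnt target lists. Other genes are said to be chosen after their values were seen, or are given as members of a list. Genes within 10 Mb of Ccrl2 were compared with the rest by Fisher's exact test.

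The test was tried on simulated counts for 13478 genes with 200 changed ones. For KO against WT, edgeR recovered 86% of the 2-fold and 100% of the 4-fold changes, with 21 false calls among 207. A list with all members shifted alike was recovered by camera with both correlations and by fry, and no other list was called. The simulated genes varied independently of one another. In the real data the estimated correlation reached 0.915 for ribosomal protein genes and 0.605 for interferon-stimulated genes. The simulation therefore does not show how the preset correlation behaves on such lists.

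Alternatives fixed beforehand were DESeq2 size factors and upper-quartile scaling in edgeR, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, no robust moderation, the replicate number as a block, protein-coding genes only, the segment around Ccrl2 left out or of another width, a prior count of 0.5, Spearman correlation, and each library left out in turn. Quality weights per library in limma-voom and lists without the genes of the leukocyte lists were added after seeing the data. Splits of the 6 libraries other than by genotype were fitted too. With 3 libraries against 3, an exact permutation test of 1 gene cannot go below p = 0.10, so single genes rest on the model fitted across genes. Some called members of the lists that did not pass are not reported here.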

Results

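RNA was sequenced from mesenchymal stromal cells (MSCs, adherent cells that can form bone, cartilage and fat in culture) of mouse alveolar bone, the jaw bone that holds the tooth sockets. Of the 6 libraries, 3 came from wild-type (WT) mice and 3 from mice lacking Ccrl2 (KO). Ccrl2 encodes an atypical chemokine receptor that binds chemerin without classical G-protein signalling. The submitters describe the cells as inflamed with TNFα and induced towards bone, and the replicates as biological, without saying whether each came from its own mouse. If they did not, the p-values measure only the spread between these cultures. Total counts lay between 16114974 in WT replicate 2 and 18616433 in KO replicate 3. Of the 54532 genes in the table, 13705 had enough counts to be tested.

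Ccrl2 was close to absent in both groups. The gene (ENSMUSG00000043953, chromosome 9, 111054486 to 111057519 on the minus strand, GRCm38 coordinates) had 4, 3 and 0 counts in WT replicates 1, 2 and 3, and 0 counts in each KO library. Summed over each group, this was 7 of 51627953 counts in WT and 0 of 51373736 in KO. Against a floor of 3 counts over the KO group, WT was 2.32-fold higher. This takes the 7 WT counts as exact, so it is no firm lower limit, and the floor covers counting error only. The gene was too low for the test. When the filter on low counts was left out, its adjusted p was 0.434 (edgeR quasi-likelihood test), so Ccrl2 gives little check of the genotype labels. Of the other genes of the chemerin pathway, the ligand gene Rarres2 (log2 fold change 0.37 ± 0.49, SE) and the receptor gene Cmklr1 (-0.53 ± 0.34) did not pass the test, with adjusted p = 0.740 and 0.488. The Y-linked gene Ddx3y had 1382 to 2280 counts in all 6 libraries and Xist 0 to 2, so both groups carried the transcripts of male cells.

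Whether TNFα had been applied cannot be settled from the counts, because no untreated cells were analysed here and the columns of the deposited table carry the word Ctrl, which no sample label has. Transcripts that TNFα induces in many cells stood at very different levels, and most of those looked at had few counts. Il6 had 3 to 25 counts per library, Cxcl10 1 to 4, Tnf 0 to 4 and Nos2 0 to 1. Cxcl2 had 0 to 2, Ccl5 3 to 11, Saa3 3 to 15, Cxcl1 1 to 16 and Lcn2 1 to 30. Cxcl5 had 7 to 102 counts, Ccl7 32 to 114, Icam1 30 to 70 and Tnfaip3 84 to 142. Ccl2, a monocyte attractant, had 74 to 108 counts in WT and 15 to 43 in KO. Vcam1, an adhesion molecule, had 1308 to 1823 counts per library and Nfkbia, an NF-kB inhibitor, 351 to 506, and in WT Csf1 stood at 1326 CPM, Ptgs2 at 141 and Nfkb1 at 116. The glucocorticoid-induced gene Fkbp5 stood at 328 ± 6.42 CPM in WT (SD, n = 3). Bglap, the osteocalcin gene of mature osteoblasts, had 0 to 3 counts per library and Bglap2 0 to 5. How reads shared between similar genes were counted is not known, so these counts may be too low. The comparison below is therefore one of genotypes under a culture condition taken from the labels.

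The comparison of KO with WT asks which transcripts differ between the genotypes, in cultures where the Ccrl2 transcript was close to absent in both. Most of the called genes were lower in KO. Macrophage and complement genes fell, as did Comp and Sox9, which are genes of cartilage, while Ibsp, Sp7 and Alpl, all genes of the osteoblast lineage, rose. Of 366 genes called at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 50 were higher and 316 lower in KO. At least 2-fold changes made up 226 of them, 16 higher and 210 lower, and 359 of the 366 were protein-coding. Over all tested genes, 1981 had an unadjusted p under 0.05, the median log2 fold change was 0.02, and the groups did not overlap in 2830 genes (20.6%, where chance gives 10%). The count of called genes depended on single libraries. It was 610 without KO replicate 2, but 158, 147 and 211 without WT replicates 1, 2 and 3, 304 without KO replicate 1 and 182 without KO replicate 3. DESeq2 called 656 genes, 123 higher and 533 lower. The split between directions depended on the settings, with 258 higher and 625 lower without the filter on low counts (29.2% higher, against 13.7% here), and 1165 higher and 1495 lower (43.8% higher) in limma-voom with library quality weights, an alternative added after seeing the data.

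KO replicate 2 stood apart from the other libraries. The first principal component held 52.1% of the variance and separated it from the rest. On this component KO replicate 2 lay at 66.6, KO replicates 1 and 3 at 3.40 and 7.76, and WT between -31.2 and -15.9. The component therefore followed the genotypes too. KO replicate 2 had 16428 genes with a count against 18928 to 19372 in the other libraries, and 2.32% of its counts were mitochondrial against 1.09% to 1.56%. Col1a1, the main collagen gene of bone matrix, had 351353 counts there against 609823 to 722879 elsewhere. Its lowest correlation with another library was 0.944 (Pearson, log2 CPM, with WT replicate 1).

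**Figure D1:**
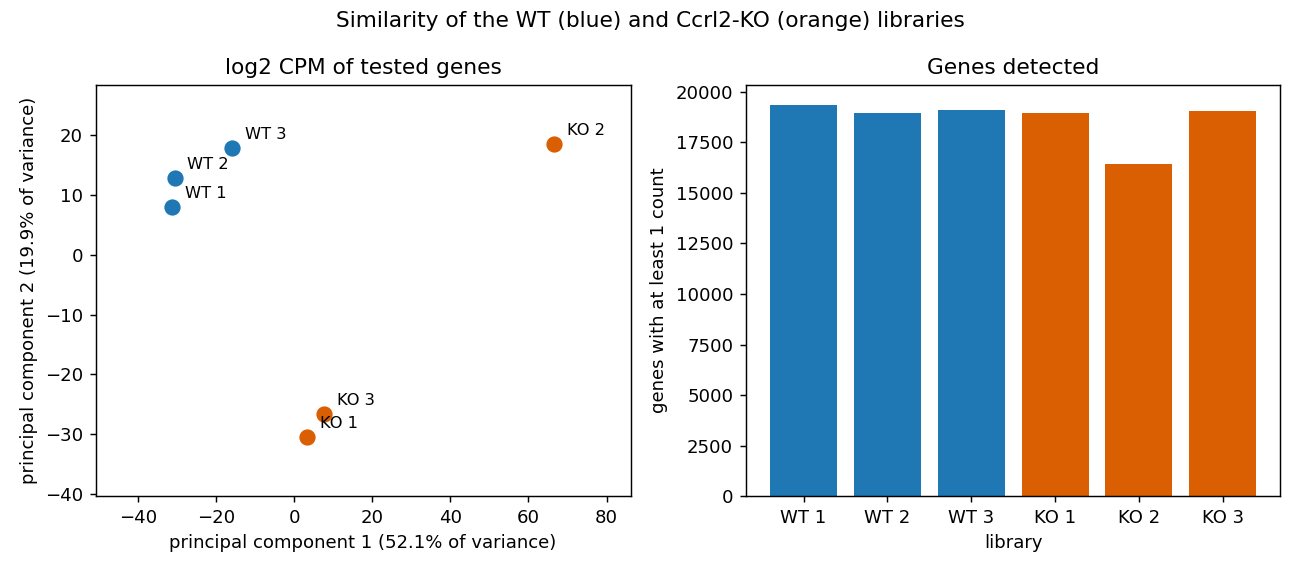
Similarity of the libraries. The left panel places each library by principal components 1 (52.1% of the variance) and 2 (19.9%) of log2 CPM over tested genes, and the right panel gives the genes with at least 1 count. KO replicate 2 lies far from the others on component 1 and has 16428 such genes.

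Among the genes with the largest rises, chosen by a rule set before the data were examined, were 3 of the osteoblast lineage. Ibsp, bone sialoprotein, rose by a log2 fold change of 2.60 ± 0.46 (SE), from 0.905 to 5.58 CPM. Sp7, the osteoblast transcription factor osterix, rose by 1.91 ± 0.30, and Alpl, tissue-nonspecific alkaline phosphatase, by 1.31 ± 0.26. The others were Adgrf5 (2.29 ± 0.27), Gzme (1.92 ± 0.38), Wdr95 (1.45 ± 0.18), Chrna1 (1.19 ± 0.20), Ackr4, another atypical chemokine receptor (1.18 ± 0.12), Glipr1 (1.15 ± 0.20) and Rgs5 (1.14 ± 0.21). Their adjusted p lay between 0.000469 for Ackr4 and 0.0254 for Alpl and Gzme. With single libraries left out, Adgrf5, Wdr95, Ackr4 and Sp7 passed each time. Alpl was lost with each library left out except KO replicate 2 (adjusted p up to 0.152). Ibsp was lost without WT replicate 2 or KO replicate 1 (adjusted p up to 0.0668). Gzme was lost without any WT library or KO replicate 3 (adjusted p up to 0.117), as was Rgs5 (up to 0.116), Chrna1 without WT replicates 1 or 2 or KO replicate 3 (up to 0.0798), and Glipr1 without WT replicates 1 or 2 (up to 0.0902).

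Most of the largest falls were in genes of leukocytes. Myo1f, a myosin of leukocytes, fell by 3.71 ± 0.54 on the log2 scale (13.1-fold lower in KO), and so did Hk3 (-3.31 ± 0.66), Fermt3 (-2.97 ± 0.66), Hpgds (-2.79 ± 0.43), Siglec1, a macrophage lectin (-2.70 ± 0.32), Ms4a6b (-2.69 ± 0.27), C1qc (-2.67 ± 0.27) and Tlr7, a sensor of single-stranded RNA (-2.66 ± 0.43). The remaining genes named by this rule were Comp, a cartilage and tendon matrix protein (-3.57 ± 0.33, 11.9-fold lower in KO), and Agtr2, an angiotensin receptor (-2.73 ± 0.18, adjusted p = 8.63e-05). Hk3 and Fermt3 were lost without any WT library or KO replicate 3 (adjusted p up to 0.138 and 0.206), and Tlr7 without WT replicate 3 (0.0521). With DESeq2 the Fermt3 log2 fold change did not pass either (adjusted p = 0.167). Among abundant transcripts, Fbln2, an extracellular matrix glycoprotein, fell from 2508 ± 216 to 1115 ± 191 CPM (SD, n = 3 per group), Igfbp4 by a log2 value of 0.90 (-0.90 ± 0.15, SE), the ferritin heavy chain gene Fth1 by 0.48 (-0.48 ± 0.10) and the fatty acid desaturase gene Scd2 by 0.50 (-0.50 ± 0.10), and the smooth muscle actin gene Actg2 rose (0.67 ± 0.11). Fbln2 was called with each library left out. Igfbp4 was lost without WT replicates 1 or 2 or KO replicate 3 (adjusted p up to 0.0740), Fth1 without any WT library or KO replicate 3 (up to 0.240), Scd2 with each library left out except KO replicate 2 (up to 0.225), and Actg2 without WT replicates 1 or 2 (0.106 and 0.113).

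**Figure D2:**
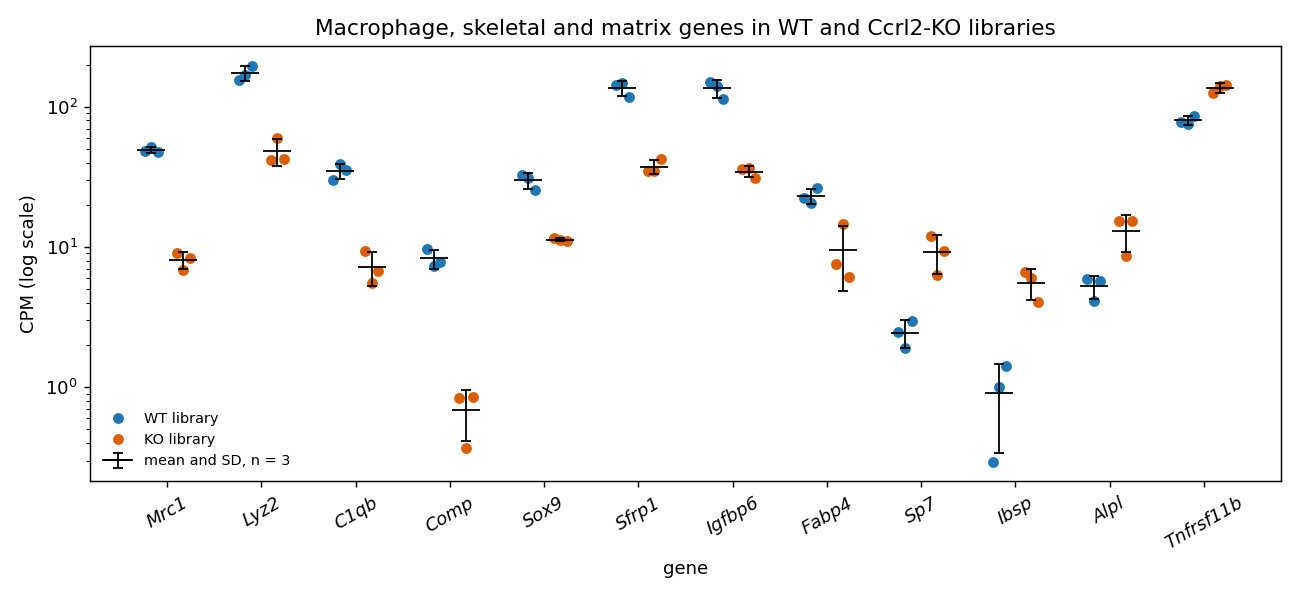
Genes of macrophages, cartilage, fat and bone, and secreted Wnt and IGF modulators, in each library. Points are CPM per library on a log axis for WT (blue) and KO (orange), with the mean and SD of 3 libraries in black. Mrc1 falls from a mean of 49.4 to 8.10 CPM and Sp7 rises from 2.45 to 9.27 CPM. The 12 genes drawn are among those named for large changes without overlap or for small p. That their groups do not overlap therefore follows from the choice and is no further evidence. Smpd3, the called osteoblast gene that fell, is not drawn.

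Gene lists were fixed before the data were examined, and 16 of the 39 that could be tested passed, 5 higher and 11 lower in KO (camera with a preset correlation of 0.01, Benjamini-Hochberg). With an estimated correlation only the macrophage and complement lists passed, and with fry 14 lists did. The estimate was below the preset 0.01 for adipogenic genes (-0.027) and antigen presentation (0.0090), which lost the threshold all the same. For these lists a higher correlation among members cannot account for the loss. For others the estimate was higher, up to 0.915 for ribosomal protein genes. The fry test lost interferon-stimulated genes (adjusted p = 0.324), antigen presentation (0.0644), oxidative phosphorylation (0.324), ribosomal protein genes (0.479) and endothelial genes (0.0999), and passed interleukins and cytokines, osteoclast coupling factors and pericyte genes, which camera did not. The macrophage list fell the most. All 19 tested members had a negative log2 fold change, 15 were called lower over all genes tested and 18 adjusted over the list alone. The mean over members was -1.97, which is 3.93-fold lower in KO (adjusted p = 1.5e-23, and adjusted p = 0.0138 with an estimated correlation). Mrc1, the mannose receptor CD206, fell by 2.61 ± 0.15 on the log2 scale (SE, adjusted p = 3.74e-05), Lyz2, lysozyme, by 1.84 ± 0.16, and Mpeg1, a pore-forming protein of phagocytes, by 2.57 ± 0.23. These were called with each library left out. The lists of neutrophils and lymphocytes had 1 tested member each, and those of mast cells and erythroid cells had none, so they were not tested as lists. The neutrophil gene Lcn2 (-2.06 ± 0.86) and the T cell gene Trac (0.90 ± 0.62) did not pass.

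Complement genes fell with the macrophage genes. Of 15 tested members, 6 were called lower over all genes tested, and 13 lower and 1 higher adjusted over the list alone, with a mean of -1.35 (2.56-fold lower in KO, adjusted p = 1.24e-11, and adjusted p = 0.0300 with an estimated correlation). C1qb (-2.27 ± 0.20) and C1qa (-2.02 ± 0.19), subunits of the C1q initiator that macrophages produce, and Serping1 (-1.50 ± 0.14), which inhibits C1, led the list. C1qa, C1qb and C1qc belong to the macrophage list too. Without these 3 genes, a choice made after seeing the data, the other 12 members averaged -1.11 (adjusted p = 3.89e-07 with the preset correlation, the estimated one not being tried). They still include C3ar1, C5ar1 and Cfp, which myeloid cells express. Among chemokine ligands, 1 of 10 tested members was called, Ccl9 (-1.04 ± 0.24, adjusted p = 0.0465), and 5 were lower adjusted over the list alone, with a mean of -0.78 (adjusted p = 0.00223, but adjusted p = 0.259 with an estimated correlation). Cxcl5 (-1.83 ± 0.50) and Ccl2 (-1.35 ± 0.40) did not pass, with adjusted p = 0.138 for Ccl2. Ccl9 was lost without WT replicates 2 or 3 or KO replicates 1 or 3 (adjusted p up to 0.180).

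The list of TNF and NF-kB targets had a small negative mean. None of its 29 tested members was called, over all genes or adjusted over the list alone, and 20 had a negative log2 fold change, with a mean of -0.21 (adjusted p = 0.0238, but adjusted p = 0.296 with an estimated correlation). The members of smallest p were Ccl2, Tapbp (-0.61 ± 0.22, adjusted p = 0.237) and the NF-kB inhibitor gene Nfkbie (-0.55 ± 0.22, adjusted p = 0.282). DESeq2 called Ccl2 (Ccl2 log2 fold change -1.35, adjusted p = 0.0357). The list passed without KO replicate 1, and was lost without any other library (adjusted p from 0.0548 to 0.112). Antigen presentation genes gave a mean of -0.27 with 0 of 13 members called (adjusted p = 0.0436, but adjusted p = 0.296 with an estimated correlation), led by Tap2 (-0.59 ± 0.20), Tapbp and H2-D1 (-0.31 ± 0.12), and were lost without WT replicates 2 or 3 (adjusted p = 0.156 and 0.0835). With single libraries left out, the mean of this list ranged from -0.47 (without WT replicate 1) to -0.19 (without WT replicate 2). For interferon-stimulated genes, 0 of 24 members were called, 23 had a negative value and the mean was -0.77 (adjusted p = 0.000397, but adjusted p = 0.679 with an estimated correlation). Stat2 (-0.90 ± 0.24), Oas2 (-2.97 ± 0.91) and Oasl2 (-2.30 ± 0.70) led them and did not pass, with adjusted p = 0.0920 for Stat2 and 0.167 for Oasl2. WT replicate 2 carried most of that difference, with a mean of 3.51 log2 CPM over the list against 2.13 and 2.32 in the other WT libraries and 1.78 to 2.06 in KO, and without it the mean was -0.35 (adjusted p = 0.0737).

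Some osteoblast genes rose and Smpd3 fell, while most members of the list were not called. Of 20 tested members, Sp7, Ibsp and Alpl were called higher and Smpd3 lower. Adjusted over the list alone, 8 were higher and 1 lower, and 6 had negative values, among them Runx2, Col1a1, Col1a2 and Sparc. The mean was 0.45 (1.37-fold higher in KO, adjusted p = 0.000885, but adjusted p = 0.296 with an estimated correlation). Smpd3, a sphingomyelinase needed for bone mineralization, fell by 0.82 ± 0.15 on the log2 scale (SE). The rising genes stood at low levels, Sp7 at 2.45 ± 0.55 CPM in WT and 9.27 ± 2.89 in KO and Alpl at 5.25 ± 1.01 and 13.1 ± 3.90 (SD, n = 3 per group), while Smpd3 was at 259 and 146 CPM. Ibsp was lost without WT replicate 2 (adjusted p = 0.0668) or KO replicate 1 (0.0502), Alpl with each library left out except KO replicate 2 (up to 0.152), and Smpd3 without WT replicates 1 or 2 or KO replicate 3 (up to 0.107). Spp1, the osteopontin gene, is mentioned for its level alone, 17817 to 27024 counts per library.

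Several cartilage genes and a few fat genes fell in the KO cultures. Of 8 tested chondrogenic genes, 5 were called lower, and 7 lower and 1 higher adjusted over the list alone, with a mean of -1.39 (2.61-fold lower in KO, adjusted p = 4.17e-07, but adjusted p = 0.202 with an estimated correlation). Comp, Sox9, the transcription factor of chondrocytes (-1.40 ± 0.15), and Prg4, lubricin of joint surfaces (-2.35 ± 0.36), led it and were called with each library left out. Col11a1 and Col2a1 were the other members called, and Sox6 (0.50) was the member higher adjusted over the list alone. Of 13 adipogenic genes, 3 were called lower, and 7 were adjusted over the list alone, with a mean of -0.72 (1.65-fold lower, adjusted p = 0.000156, but adjusted p = 0.134 with an estimated correlation). They were Ebf2, a factor of preadipocytes (-2.14 ± 0.32), Cebpd, an early adipogenic factor (-0.99 ± 0.18), and Fabp4, a fatty acid carrier (-1.30 ± 0.28), whereas Pparg (0.39) and Agpat2 (0.04) had positive values and were not called. Macrophages express Fabp4 too, and the macrophage list was lower in the same cultures (mean -1.97). Cebpd was lost without any WT library or KO replicate 3 (adjusted p up to 0.102) and Fabp4 with each library left out except KO replicate 2 (up to 0.151). Without the filter on low counts both lists still passed camera, with means nearer to no change. The chondrogenic mean was then -0.72 over 16 members (adjusted p = 0.000598) and the adipogenic mean -0.46 over 17 (adjusted p = 0.00722).

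Some secreted Wnt and IGF modulators fell, among them Sfrp1, Sfrp2, Dkk2 and Igfbp6, while most members of their lists were not called. Of 17 Wnt ligands and inhibitors, 4 were called lower, and 6 lower and 3 higher (Wif1, Wnt11 and Dkk3) adjusted over the list alone, with a mean of -0.29 (adjusted p = 0.0415, but adjusted p = 0.324 with an estimated correlation). The list was lost with each library left out except KO replicate 3 (adjusted p up to 0.202, without KO replicate 2). Sfrp1 (-1.86 ± 0.13, 136 ± 16.9 CPM in WT against 37.5 ± 4.30 in KO), Sfrp2 (-1.32 ± 0.18) and Dkk2 (-0.98 ± 0.12) encode secreted proteins that bind Wnt ligands or their co-receptors and are mostly inhibitory, and Rspo3 (-1.96, adjusted p = 0.0195) encodes an enhancer of Wnt signalling. The targets of Wnt and β-catenin did not pass as a list. Of 19, Tnfrsf11b, osteoprotegerin, was called higher (0.77 ± 0.11) and Dkk2 lower, while Lgr6 (1.32 ± 0.33) had adjusted p = 0.0721. Adjusted over the list alone, 5 were higher and 4 lower. Their mean was 0.06, their median -0.02 and the direction of camera was down (adjusted p = 0.970). In the list of PI3K, AKT and insulin-like growth factors, 2 of 19 were called lower, Igfbp6 (-1.97 ± 0.14) and Igfbp4, both binding proteins of these factors, and 5 adjusted over the list alone. The mean was -0.26 (adjusted p = 0.0102, but adjusted p = 0.457 with an estimated correlation), and Foxo3 (-0.46 ± 0.11) had adjusted p = 0.0591. This list was lost without WT replicate 1 (adjusted p = 0.0725). Among 5 endothelial genes, the VEGF receptor gene Flt1 was called lower (-0.92 ± 0.13), 3 were lower adjusted over the list alone, and Ecscr (-0.71 ± 0.25) and Kdr (-1.23 ± 0.45) had adjusted p = 0.226 and 0.241. The list mean was -0.55 (adjusted p = 0.0415, but adjusted p = 0.302 with an estimated correlation), and it was lost without WT replicate 1 or KO replicates 1 or 2 (adjusted p up to 0.104).

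The lists that rose beside the osteoblast genes did so by small amounts and without called members. Cell cycle genes averaged 0.23 over 30 members, 27 of them positive (adjusted p = 0.000191, but adjusted p = 0.296 with an estimated correlation), led by the replication genes Mcm5 (0.45 ± 0.13) and Mcm6 (0.31 ± 0.10) and the mitotic kinesin gene Kif11 (0.42 ± 0.14). Genes of the unfolded protein response averaged 0.17 over 21 members (adjusted p = 0.0102, but adjusted p = 0.296 with an estimated correlation). Adjusted over the list alone, 2 were higher and 1 was lower, led by Asns (0.48 ± 0.11, adjusted p = 0.0508), Chac1 (0.69 ± 0.16, adjusted p = 0.0565) and Edem1 (-0.40 ± 0.10, adjusted p = 0.0616), and the list was lost without WT replicate 1 (adjusted p = 0.0590). Oxidative phosphorylation genes averaged 0.34 over 25 members (adjusted p = 0.00151, but adjusted p = 0.686 with an estimated correlation), led by Ndufb5 (0.55 ± 0.23), Atp5g1 (0.48 ± 0.20) and Sdhb (0.36 ± 0.16). Ribosomal protein genes averaged 0.29 over 30 members (adjusted p = 0.00182, but adjusted p = 0.773 with an estimated correlation), led by Rps6 (0.37 ± 0.19), Rps3 (0.30 ± 0.18) and Rpl14 (0.43 ± 0.26). KO replicate 2 set both of these. Its mean over the ribosomal list was 9.54 log2 CPM against 8.55 to 8.92 in the other libraries, and over the oxidative phosphorylation list 6.62 against 5.68 to 6.02. Without it their means were 0.02 (adjusted p = 0.689) and 0.11 (adjusted p = 0.0904). Ribosomal protein genes have many near-identical pseudogenes, so their counts depend on how shared reads were assigned.

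**Figure D3:**
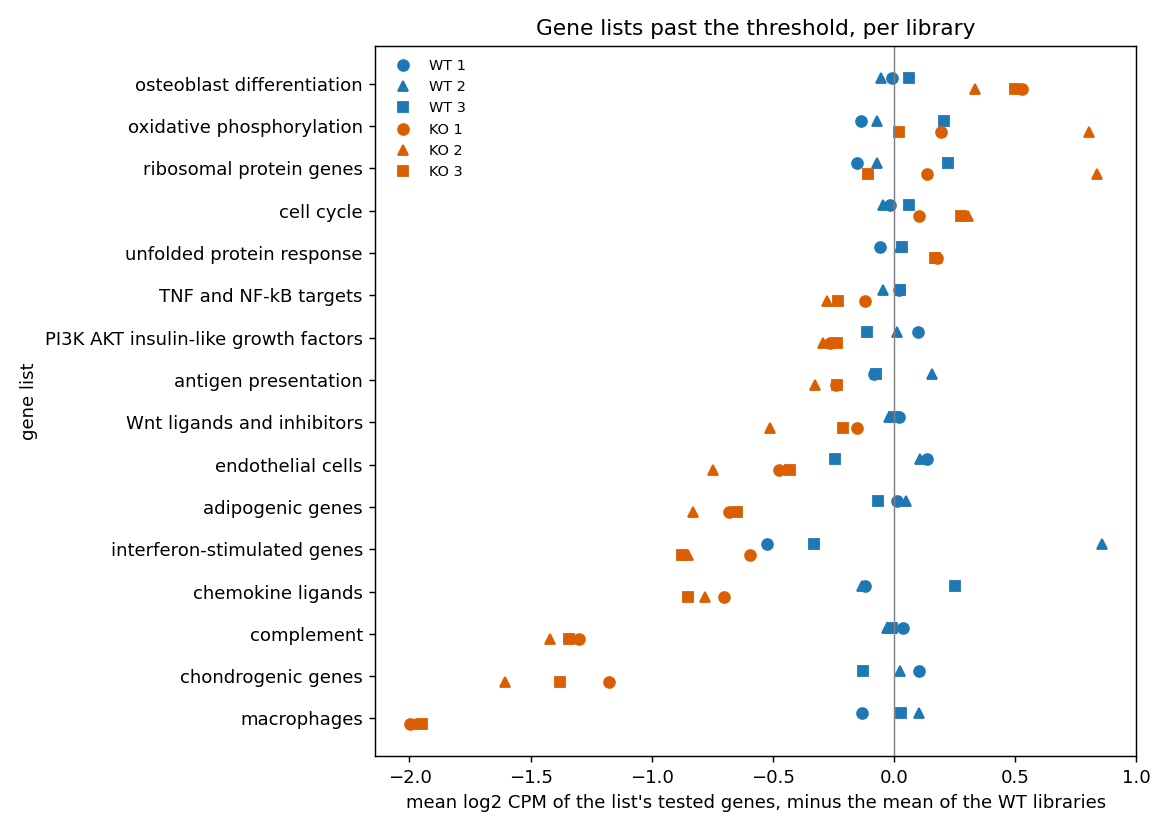
Gene lists past the threshold with a preset correlation. Each point is the mean log2 CPM of a list's tested genes in 1 library minus the mean of the WT libraries, for WT (blue) and KO (orange), with a marker shape per replicate number. The macrophage list lies near -2 in each KO library, WT replicate 2 lies above the other libraries in interferon-stimulated genes, and KO replicate 2 lies above them in ribosomal and oxidative phosphorylation genes.

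The other 23 tested lists did not pass, and 16 of them held called genes, of which those named here were chosen after their values were seen. Stromal and MSC markers went both ways, with 1 of 20 called higher (Nes) and 3 lower (Thy1, Alcam and Grem1) and a mean of -0.02. Adjusted over the list alone, 3 were higher and 7 lower. Among BMP and TGF-β genes, Tgfb2 was called higher and Id4 and Grem1 lower. Among matrix genes Ogn was higher, and among matrix proteases and inhibitors Timp3 was higher and Adamts5 lower. Il1rl1, the IL-33 receptor, was higher among interleukins and cytokines, and Tnfrsf11b among osteoclast coupling factors. Thbs4 was lower among ligament and tendon genes, Fos among immediate early genes, Sod3 among NRF2 and oxidative stress genes and Cebpd among glucocorticoid-responsive genes. Pax9, Msx1 and Lhx6, transcription factors of the developing jaw and teeth, were lower among homeobox and positional genes. The dental list had called genes in both directions, such as Nes higher and Msx1 lower. Rgs5 was higher among pericyte genes, Chrna1 among skeletal muscle genes, and Stmn2 was higher and Pmp22 lower among Schwann cell and neuron genes. Lists of osteocyte genes, p53 targets, glycolysis, cholesterol synthesis, Notch, osteoclasts and epithelium held none at an adjusted p under 0.05. The adjusted p of these 23 lists lay between 0.0827, for Schwann cells and neurons, and 0.970, for Wnt and β-catenin targets. The signs of mean, median and test were not all the same for stromal markers, BMP and TGF-β, homeobox, glycolysis, skeletal muscle, epithelial and dental genes. Without KO replicate 2, the Schwann cell and neuron list (mean 0.64, adjusted p = 0.00187) and the pericyte list (mean 0.17, adjusted p = 0.0243) passed. The first also passed without WT replicate 1 (0.53, adjusted p = 0.0456), and immediate early genes did without KO replicate 1 (-0.22, adjusted p = 0.0301).

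Genes around the deleted locus were not called more often than others. Within 10 Mb of Ccrl2 on chromosome 9, where a knockout can retain DNA of the strain it was made in, 2 of 176 tested genes were called (1.14%), against 364 of 13529 elsewhere (2.69%), an odds ratio of 0.416 (Fisher's exact test, two-sided, p = 0.339). These were Ackr4 (104084157 to 104126933), which was higher, and Sema3f (107681500 to 107710475, -0.91 ± 0.11), which was lower in KO. Without WT replicate 2 the odds ratio was 1.07 (Fisher's exact p = 0.711).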

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

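The alternatives here were chosen before the data were examined, except library quality weights and the lists without the genes of the leukocyte lists. No gene of the 366 called changed sign under any setting of the gene test. Without a filter on low counts 883 genes were called, 258 higher and 625 lower, and 366 of the 883 were those of the report. DESeq2 called 656 (123 higher, 533 lower, 365 shared) and limma-voom with quality weights 2660 (1165 higher, 1495 lower, 630 at least 2-fold, 366 shared), where the odds ratio of genes near Ccrl2 was 0.559 (Fisher's exact p = 0.00953, from 0.00953 to 1 over the alternatives). The genes changed at least 2-fold in KO against WT were 385 without the filter. The cause was not tested for these. Other scalings, a stricter filter, limma-voom and no robust moderation gave 337 to 377 genes. With 1 library left out, and so fewer samples, the genes called ranged from 147 (without WT replicate 2) to 610 (without KO replicate 2), those higher from 12 to 118, those lower from 135 to 492, and those at least 2-fold from 126 (without WT replicate 2; 135 without WT replicate 1) to 302. The odds ratio near Ccrl2 ranged from 0.496 to 1.07 (without WT replicate 2), the mean of the TNF and NF-kB list from -0.26 to -0.15 and that of the Wnt beta-catenin targets from 0.0056 (without KO replicate 3) to 0.23. Camera's direction for the Wnt targets turned up without a filter (0.14), with the replicate block (0.063) and without WT replicates 1 to 3 or KO replicate 2. Without a filter the NF-kB list missed the threshold (-0.17, adjusted p = 0.0761). With an estimated correlation 2 lists passed, and neither the osteoblast list (0.45, adjusted p = 0.296) nor the NF-kB list (-0.21, 0.296) did. The replicate block called 331 genes (39 higher, 292 lower, 303 shared) and 14 lists, losing antigen presentation (adjusted p = 0.0538), Wnt ligands and inhibitors (0.0643) and endothelial genes (0.0756) and gaining Schwann cells and neurons (0.0324). Without a filter the Wnt ligands and inhibitors (0.0653) and endothelial genes (0.0705) were lost too and Schwann cells and neurons gained (0.0366). Same-numbered libraries deviated with correlations of 0.137, -0.105 and -0.192, which gives no sign that the numbers pair the samples. Deviations from a mean of 3 libraries are not independent, so a pairing cannot be excluded. The lowest correlation between libraries was 0.961 by Spearman. Of the named genes' other values 1052 kept their side of the threshold, 66 lost it and 52 passed it newly, and of the other called lists' values 158 kept it and 37 lost it, with no reversal. Of 44 named genes called, 27 passed with each library left out, and of 16 lists 7. Ccrl2 was too low for DESeq2, limma-voom and the block to give a value. Depth limits Ccrl2 and genes under about 0.5 CPM.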

Other observations

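The tests on sequencing depth, on the osteoblast list and on other splits were chosen after the result was seen, and those on leukocytes, gene length and adventitial fibroblasts before it. The genes in this paragraph were chosen after their values were seen. Outside the lists, some of the smallest p-values belonged to genes that were lower in KO, and their cell type of origin was not tested. Tinagl1, a matrix protein of basement membranes, fell by 1.95 ± 0.11 on the log2 scale (SE, n = 3 per group, adjusted p = 3.74e-05), Cdkn1c, a cell cycle inhibitor, by 2.08 ± 0.16, Selenop, a selenium carrier that tissue macrophages express too, by 1.57 ± 0.11, Scara5, a ferritin receptor, by 1.80 ± 0.14, and the growth factor gene Fgf10 by 1.76 ± 0.16. Among prostaglandin enzymes, Ptgis, the prostacyclin synthase, fell by 1.58 ± 0.12 and Ptgs1 by 1.11 ± 0.11, whereas Ptgs2 did not pass (-0.13, adjusted p = 0.696). Receptors of the interleukin-1 family were called in both directions. Il1rl1 rose from 57.0 to 110.4 CPM (0.95 ± 0.13), and Il1r1 (-0.65 ± 0.12) and Il1rap (-0.81 ± 0.13), which encode the receptor for interleukin-1 and its partner chain, fell. The scavenging chemokine receptor genes Ackr4 and Ackr3 were called in opposite directions (1.18 ± 0.12 and -1.06 ± 0.16), while Ccrl2 itself was near the floor.

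The macrophage list was lower in each KO library than in each WT library. As a hypothesis, the KO cultures may have held fewer macrophages or other leukocytes. A second list of 38 leukocyte genes, with none from the first list, had 33 tested members, of which 31 were lower and 17 called lower, with a median log2 fold change of -1.80, as this explanation needs. No share of cells was estimated. Whether such a share differed because Ccrl2 is missing or because of how the cultures were prepared cannot be said from 3 cultures a genotype, and changed expression within macrophages was not tested.

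A lower share of macrophages could raise all stromal genes alike, and so the osteoblast list. The osteoblast list lay 0.46 above the stromal and MSC list in mean log2 fold change (0.46 against 0.00, 20 members each, permutation p = 0.0434 over genes, which are not independent replicates). The difference is smaller than the SD of 0.60 among the stromal members, which went both ways. The test's own limit for rejecting this explanation was therefore not met. That SD is the spread of single genes, not the error of a list mean, and the osteoblast list had already been seen to be higher. The stromal mean of 0.00 is the value already used in that difference. Among 28 matrix genes, 21 had negative values and 7 positive (mean -0.05). These 2 lists thus did not share the osteoblast list's mean. TMM scaling holds most genes near no change (median log2 fold change 0.02 over all tested genes). Means near 0 therefore cannot show whether all stromal genes rose together, and no conclusion on this explanation is drawn. A change in the cells' state, a different mix of stromal cells and the genotype itself stay open and were not tested for this list.

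KO replicate 2 stood apart in detected genes, mitochondrial share and ribosomal protein genes. At equal totals of 16114974 counts it still had 16427 genes with a count against 18869 to 19258 in the others, which argues against sequencing depth. RNA degradation or another library bias by gene length may be involved. The deviation of this library from the other KO libraries correlated with gene length by a Spearman rho of -0.11 over 13705 genes, weaker than the rho of -0.25 between KO replicates 1 and 3, a value too small to argue for it and too large to exclude it. No biological explanation was tested.

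As a further hypothesis, fewer cells of an adventitial fibroblast type may be present in the KO cultures, since some genes that fibroblasts express, such as Fbln2, were lower. A list of 28 genes of such cells, written before its values were seen, had 20 tested members with a mean log2 fold change of -0.25 and a median of -0.54. Camera gave p = 0.0437 with an estimated correlation, 13 members were lower, 4 were called lower and 1 higher (Pcolce2). The list of matrix genes in the report did not pass (mean -0.05, adjusted p = 0.291), and its only called member, Ogn, was higher. The evidence is thin, and cultured stromal cells express many of these genes too.

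With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The split by genotype gave 366 genes and the highest of the others 0 (edgeR), and it was 1 of 10 with as many. For genes changed at least 2-fold the values were 226 and 0, again 1 of 10, and for gene lists 16 and 6, again 1 of 10. In the other 9 splits 88 to 1930 genes had an unadjusted p under 0.05 and DESeq2 called 0 to 52. Each of these 9 mixed the genotypes, so a genotype difference would widen the spread within their groups and lower their calls. Their low counts therefore say little about what grouping by chance would give.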
